A study of Homo sapiens with 12 samples.

How the data were processed

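The samples were 12 single-cell RNA libraries from human mammary epithelial cells. Per the labels, cells were grown inside a ring of 3.2 mm diameter, the ring was removed, and the colony was collected after 7 days as an inner and an outer part. Cultures were left untreated or given TGF-B1 at 4 ng/mL, renewed every 48 hours. The 3 experiments were MCF10A, a spontaneously immortalised breast epithelial line, MCF10A carrying Cas9 and a pooled guide library read out by CROP-seq (a vector that places each guide in a polyadenylated transcript), and HuMEC, primary human mammary epithelial cells. Each experiment had 1 library for each combination of treatment and position, so no library had a replicate of its own group. Replication came from the 6 inner and outer pairs and the 6 treated and untreated pairs across experiments, and p-values measure only the spread between these pairs, which may be technical. The inner and outer parts of a colony share its treatment, and the TGF-B1 tests count the 2 parts as independent. Whether a pair of parts came from 1 colony or a pool of several is not given in the sources used here. Below, a colony means the culture behind an inner and an outer library, 3 treated and 3 untreated.

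The authors deposited 3 matrices of UMI counts per gene and cell, made with Cell Ranger against hg19 per the submitters' processing notes, with no version named, after a 10x Genomics droplet kit per the labels' protocols. The authors also deposited 3 cell tables, which give the library of each cell, its total UMI count and, in the CROP-seq experiment, the guides and their target genes. How guides were assigned to cells is not given in the sources used here. The matrices held 32738 genes, in which 91 symbols belonged to more than 1 gene ID. Gene IDs were kept apart, and such a symbol names the ID with the most counts. The MCF10A matrix held 23951 cells by barcodes from 10 libraries. The MCF10A cell table named 9268 cells, 9238 of them in the matrix and 30 absent from it. The remaining 14713 matrix cells had no library in the table and were not used here. The ratio of matrix to table UMIs per cell was 0.735 in the MCF10A untreated outer library, 0.974 in the untreated inner, 1.00 in the TGF-B1 inner and 0.950 in the TGF-B1 outer library. The ratio was 1 in the other 8 libraries. The cause of the lower ratios is not given in the sources used here. The CROP-seq matrix held 29432 cells and the HuMEC matrix 22352. The cell tables held no position along a fitted trajectory, so that intended result gives no values.

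Counts were summed over the cells of each library. Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the quasi-likelihood test, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05, over 15202 genes. Outer against inner was fitted with the 6 pairs of experiment and treatment as a block, and TGF-B1 against untreated with the 6 pairs of experiment and position as a block. Differences of these effects between treatments, and between HuMEC and the MCF10A libraries, came from the same kind of fit with separate effects for each. Standard errors (SE) are of log2 fold changes. CPM is a gene's UMI count scaled to the total count of its library in the usual way.

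Gene lists, 24 in number, were tested with fry, which asks whether the members of a list move one way on balance, and with camera using a correlation estimated from the data, which compares a list with all other genes. Both p-values were Benjamini-Hochberg adjusted over lists. The lists cover epithelial junction and polarity, basal and stratified keratins, simple and luminal epithelial genes, hemidesmosome genes, mesenchymal markers, fibrillar and basement membrane matrix, matrix proteases and their inhibitors, TGF-beta direct targets, actin and contractile genes, YAP and TEAD targets, S phase, G2 and M phase, stratified differentiation and defence, interferon-stimulated genes, cytokines and chemokines, hypoxia and glycolysis, cholesterol synthesis, p53 targets, immediate early and heat shock genes, ribosomal proteins, mitochondrially encoded genes, and markers of fibroblasts, leukocytes and endothelial cells.

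A mesenchymal minus epithelial score was computed per cell as the mean log2(count + 1) over 64 mesenchymal and matrix genes minus that over 36 epithelial junction genes, after each cell had been thinned to 2900 UMIs. The medians per library were compared over 6 pairs by an exact two-sided sign-flip test, whose 64 sign patterns allow no p below 0.03125.

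In the CROP-seq experiment, 23805 cells carried 1 guide and were used for the guide comparisons, which covered 40 targets and 249 guides, 14 of them non-targeting. The 2379 cells with more than 1 guide and the 3248 with none were left out of them. No doublet caller was run. Counts were summed per target and library for the 39 targets with at least 20 cells in each of the 4 libraries, which left out FGFR1, with 18 cells in the TGF-B1 outer library. The sums were fitted with library and target by treatment terms over 7896 genes, with non-targeting cells as reference. The p-values of a target measure only the spread between inner and outer libraries. This spread was pooled per gene over all targets and both arms, so it is not the target's own. List p-values for targets were adjusted over all targets, arms and lists together. A TGF-B1 response index was the projection of the log2 ratio of target to non-targeting cells on the 458 genes that changed at least 1 log2 unit the same way in both MCF10A pairs without guides, with at least 50 CPM in 1 library. A value of 0 is the non-targeting level and -1 the loss of a response of the size seen in MCF10A. A position index used 101 genes chosen alike. Odds ratios of outer to inner cells, relative to non-targeting guides, have exact conditional 95% intervals that cover counting error only.

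Genes are named by a rule. For position and TGF-B1 these are the 12 largest rises and the 12 largest falls among called genes with the same sign in all 6 pairs and at least 20 mean CPM, 14 genes always named (VIM, FN1, CDH1, CDH2, EPCAM, KRT5, KRT14, KRT17, TGFBI, ZEB1, SNAI2, SPARC, COL1A1 and 1 that is not reported here), and up to 4 members of each list. For differences between effects they are the 6 largest per direction with at least 20 mean CPM, and for guide targets the 3 largest per direction for TGFBR1, TGFBR2, the 5 other targets with most calls in the TGF-B1 arm and the 3 with most in the untreated arm. XIST and Y-linked genes were left out. Where 5 or fewer genes were called, others were named after their values were seen. The groups, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, its size factors, library size alone, other filters, cells with high or low UMI counts left out, thinning to 23909954 UMIs per library, each pair or library left out, the MCF10A libraries alone, additive terms in place of the pair block, limma-voom, guides as units, and other signatures and references. The CROP-seq libraries reduced to their non-targeting cells, and a newer form of edgeR's quasi-likelihood fit for guide targets, were added after the data had been seen. So were TGF-B1 fits with the inner and outer parts summed per colony. Tests of a target's effect between arms, and of TGFBR2 against TGFBR1 guides, were not among those fixed beforehand.

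Total counts per library ran from 23909954 to 112301152 UMIs, and this depth sets the counting error of genes with few UMIs. The fits were tested on simulated data. For outer against inner, 100 of 100 genes with a log2 change of 1 and 30 of 100 with a change of 0.5 were recovered, with 10 false calls among 15202 genes. For a target with 160 cells, 94 of 100 genes with a log2 change of 1 and 98 of 100 with a change of 2 were recovered, with 4 false calls among 7896. The simulated changes were the same in all pairs or libraries, and the genes with the lowest counts were not drawn. The recovery thus does not hold for effects that differ between experiments. CDH1, for instance, had -1.07 for position and was not called. Indices, odds ratios and permutation tests were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots with Matplotlib 3.10.9.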

Results

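Transcripts were counted in single human mammary epithelial cells to ask how expression changes from the centre to the edge of a spreading colony, and after TGF-B1, a cytokine that induces epithelial-to-mesenchymal transition. The MCF10A, CROP-seq and HuMEC experiments each gave an inner and an outer library of an untreated and of a TGF-B1 colony, 1 library per group. The untreated MCF10A colony gave 23909954 UMIs from 2440 cells in its inner and 26409907 UMIs from 2564 cells in its outer library, and the TGF-B1 colony 26356593 from 2121 and 28219559 from 2113. The untreated CROP-seq colony gave 111008250 UMIs from 9068 inner and 112301152 from 8025 outer cells, and the TGF-B1 colony 79461620 from 5909 and 99310607 from 6430. The untreated HuMEC colony gave 50817656 UMIs from 6096 inner and 47644220 from 5812 outer cells, and the TGF-B1 colony 37134433 from 4357 and 55525393 from 6087. Median UMIs per cell ran from 7820 in the HuMEC untreated outer library to 15350 in the CROP-seq TGF-B1 outer library, and mitochondrial transcripts took 2.39% to 4.43% of the counts of a library. Markers of other cell types were low, at 49.0 to 264 summed CPM for fibroblast genes, 15.5 to 114 for leukocyte genes and 0.413 to 26.6 for endothelial genes, against 1377 to 6976 for the epithelial junction genes. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, written as edgeR adjusted p.

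The largest rises from the centre to the edge of the colony included single matrix, contractile and chemokine genes, and the largest falls genes of the cornified layer. TAGLN, an actin-binding protein of contractile cells, rose by 1.92 on the log2 scale (SE 0.22, edgeR adjusted p = 0.0044, higher in 6 of 6 pairs), and THBS1, an adhesive glycoprotein of wounded tissue, rose by 1.77 (SE 0.17, edgeR adjusted p = 0.00190). The short-chain collagen gene COL8A1 rose by 2.19 (SE 0.32) and the basement membrane collagens COL4A1 and COL4A2 by 1.47 (SE 0.21) and 1.59 (SE 0.24). S100P, a calcium-binding protein, fell by 2.64 (SE 0.22, edgeR adjusted p = 0.00190), from a mean of 273 to 48.6 CPM. The proteases and structural proteins of the cornified envelope CASP14, KLK11, SBSN and SCEL had log2 fold changes of -2.17 (SE 0.43), -2.06 (SE 0.40), -2.33 (SE 0.47) and -2.06 (SE 0.33), and the tight junction gene CLDN4 one of -2.01 (SE 0.43). The growth factor and chemokine genes CSF3, CXCL1 and IL8 rose by 1.80 (SE 0.33), 1.56 (SE 0.24) and 1.40 (SE 0.28), and the secreted matrix protein gene CTGF by 1.55 (SE 0.29). Of the 14 genes named in every comparison, FN1, which encodes fibronectin, rose by 1.91 (SE 0.46, edgeR adjusted p = 0.0300, higher in 5 of 6 pairs), SPARC by 1.57 (SE 0.38) and the repressor gene ZEB1 by 0.78 (SE 0.20). The basal keratins KRT17 and KRT5 had -1.13 (SE 0.24) and -0.36 (SE 0.07).

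Vimentin (VIM) had 0.58 (SE 0.17, edgeR adjusted p = 0.0559) in the outer colony and N-cadherin (CDH2) 1.03 (SE 0.29, edgeR adjusted p = 0.0568), higher in 6 and 5 of 6 pairs and not called. E-cadherin (CDH1) had -1.07 (SE 0.34, edgeR adjusted p = 0.0699) and was higher in 2 of 6 pairs, and COL1A1 had -0.59 (edgeR adjusted p = 0.0676). EPCAM had -0.47, KRT14 -0.09, TGFBI 0.08 and SNAI2 0.18, with edgeR adjusted p = 0.185, 0.823, 0.742 and 0.212. Without the HuMEC TGF-B1 pair CDH1, VIM and COL1A1 were called, at -1.31, 0.69 and -0.75, as was CDH2 without the CROP-seq TGF-B1 pair, at 1.39. Of 15202 genes, 1707 were called, 862 higher and 845 lower in the outer colony. Scaling by library size alone called 1622, 1055 higher and 567 lower. The count fell to 680 without the CROP-seq TGF-B1 pair, 1129 without the CROP-seq untreated pair, 821 without the MCF10A TGF-B1 pair and 804 without the MCF10A untreated pair. The 28 called genes of the naming rule included 13 that missed the threshold when 1 pair was left out. Their highest edgeR adjusted p were 0.113 for INHBA, 0.105 for ZEB1, 0.0966 for KRT5 and 0.0689 for SPARC without the MCF10A TGF-B1 pair. Without the CROP-seq TGF-B1 pair they were 0.0765 for CALML5, 0.0746 for KLK10, 0.0566 for KLK7, 0.0752 for SPRR1A and 0.0575 for KRT17, and without the MCF10A untreated pair 0.0797 for FN1, 0.0780 for KLK5, 0.0629 for CXCL3 and 0.0525 for UNC5B-AS1. The log2 fold changes of those not given above were 1.37 for INHBA, 2.35 for CXCL3, -2.85 for CALML5, -2.34 for KLK10, -2.61 for KLK7, -2.29 for SPRR1A, -3.23 for KLK5 and -2.72 for UNC5B-AS1. Near-identical copies can share reads, as in the SPRR, CXCL and KRT6 families, and UNC5B-AS1 can share them with UNC5B, since the use of strand in counting is not stated.

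**Figure D1:**
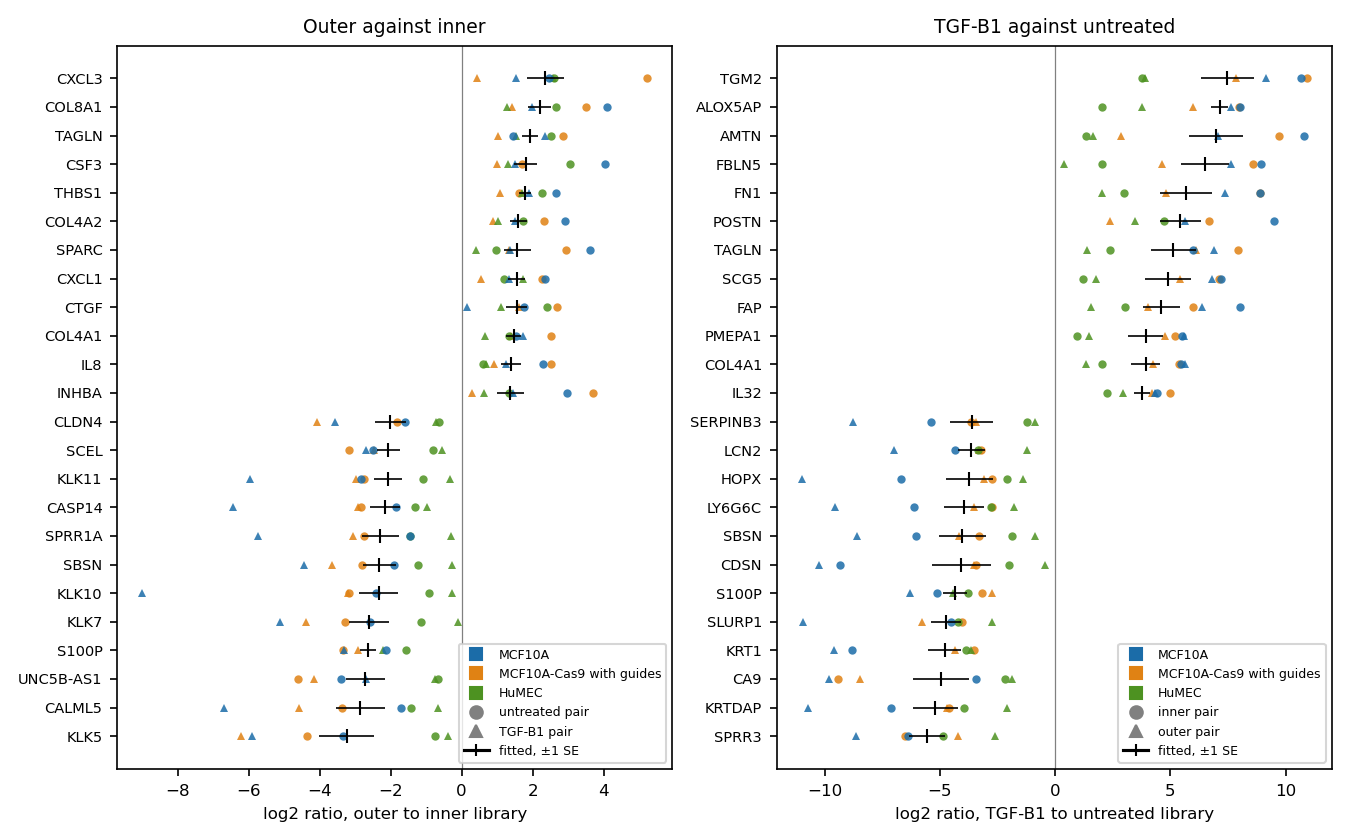
Log2 ratios of the genes with the largest rises and falls in each of 6 pairs (points, coloured by experiment) with the fitted log2 fold change and its SE (black), for outer against inner (left) and TGF-B1 against untreated (right). All pairs of each gene lie on 1 side of 0, and the fitted values run from -3.23 (KLK5) to 2.35 (CXCL3) on the left and from -5.55 (SPRR3) to 7.46 (TGM2) on the right.

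Epithelial and cornified genes fell as groups in the outer colony, and cell cycle and cytokine genes rose. Of 36 epithelial junction genes, 27 were lower over all genes and 31 adjusted over the list alone (median log2 fold change -0.84, fry adjusted p = 0.0146, adjusted p = 0.130 with an estimated correlation). ELF3, an epithelial transcription factor gene, had -3.71 (SE 0.72), RAB25, a regulator of polarised transport, -1.46 (SE 0.28), and GRHL1, a regulator of epidermal junctions, -1.47 (SE 0.27). Stratified differentiation genes had a median of -1.41 (16 of 29 lower, 21 adjusted over the list alone, fry adjusted p = 0.0146, adjusted p = 0.127 with an estimated correlation). Basal and stratified keratins had -1.30 (6 of 11 lower, 10 adjusted over the list alone, fry adjusted p = 0.0146, adjusted p = 0.127 with an estimated correlation). Among them KRT4 stood at -3.14 (SE 0.50) and the wound keratin KRT16 at -1.72 (SE 0.31). G2 and M phase genes rose by a median of 0.74 (20 of 23, 22 adjusted over the list alone, fry adjusted p = 0.00774, adjusted p = 0.127 with an estimated correlation), among them the mitotic kinase gene BUB1 at 1.02 (SE 0.14). S phase genes rose by 0.45 (13 of 21, 18 adjusted over the list alone, fry adjusted p = 0.0146, adjusted p = 0.131 with an estimated correlation). CLSPN, a checkpoint gene, had 1.10 (SE 0.13). Cytokines and chemokines rose by a median of 0.90 (8 of 19 higher and 1 lower, 11 and 1 adjusted over the list alone, fry adjusted p = 0.00522, adjusted p = 0.0562 with an estimated correlation). The colony-stimulating factor gene CSF2 had 2.21 (SE 0.31). Hypoxia and glycolysis genes had a median of -0.36 (8 of 21 lower, 11 adjusted over the list alone, fry adjusted p = 0.00774, adjusted p = 0.127 with an estimated correlation). The oxygen sensor gene EGLN3 had -1.47 (SE 0.14) and the stress gene NDRG1 -1.24 (SE 0.18).

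Mesenchymal markers had a median of 0.53 in the outer colony (8 of 23 called higher, fry adjusted p = 0.0146). TGF-beta direct targets had 0.11 (4 of 30 higher and 2 lower) and actin genes 0.20 (2 of 18), each with fry adjusted p = 0.00774. For these 3 lists the adjusted p was 0.127 with an estimated correlation. Matrix genes had 0.28 (7 of 34 higher and 2 lower, fry adjusted p = 0.0267, adjusted p = 0.205 with an estimated correlation). YAP and TEAD targets had 0.24 (4 of 18, fry adjusted p = 0.0267, adjusted p = 0.275 with an estimated correlation). Immediate early and heat shock genes had -0.44 (8 of 24 lower and 2 higher, fry adjusted p = 0.0250, adjusted p = 0.205 with an estimated correlation). The p53 targets had -0.12 (4 of 20, fry adjusted p = 0.0250, adjusted p = 0.283 with an estimated correlation). Adjusted over the list alone, these counts were 10 mesenchymal genes higher and 1 lower, 7 and 2 TGF-beta targets, 2 actin genes, 10 and 3 matrix genes, 7 YAP targets, 5 immediate early genes higher and 10 lower, and 7 p53 targets. Leaving out 1 pair raised the fry adjusted p to 0.0678 for YAP targets and for immediate early genes and 0.0717 for p53 targets (without the HuMEC TGF-B1 pair), 0.0955 for matrix genes (HuMEC untreated) and 0.0598 for mesenchymal markers (MCF10A untreated). Lists that missed the threshold were simple epithelial genes (median -0.21, fry adjusted p = 0.350), hemidesmosome genes (0.06, 0.281), matrix proteases (0.14, 0.528), interferon-stimulated genes (-0.11, 0.375), cholesterol synthesis (0.07, 0.666), leukocyte markers (-0.44, 0.100), ribosomal proteins (-0.16, 0.152) and mitochondrially encoded genes (-0.09, 0.528). The fibroblast and endothelial lists had too few genes tested. Of the 2 fibroblast markers tested, FBLN1, at a mean of 96.8 CPM, had 0.15 (edgeR adjusted p = 0.760). DCN, with 0 CPM in HuMEC, had -1.41 (edgeR adjusted p = 0.0456), a call lost without any 1 of 4 pairs (up to 0.139). The endothelial marker CLDN5, with 0 CPM in the MCF10A libraries, had -1.49 (edgeR adjusted p = 0.0282, but 0.147 without the HuMEC TGF-B1 pair).

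The largest rises with TGF-B1 included single matrix and cytoskeletal genes, and the largest falls genes of the cornified layer. TGM2, a protein cross-linking enzyme, rose by 7.46 on the log2 scale (SE 1.15, edgeR adjusted p = 0.00470), from a mean of 0.820 to 212 CPM, and FN1 by 5.68 (SE 1.13, edgeR adjusted p = 0.0107), from 42.5 to 969 CPM. ALOX5AP, a leukotriene pathway gene, rose by 7.14 (SE 0.36), the basement membrane gene AMTN by 6.98 (SE 1.15) and the elastic fibre gene FBLN5 by 6.52 (SE 1.05). The matricellular gene POSTN rose by 5.43 (SE 0.89), TAGLN by 5.13 (SE 0.99) and the surface protease FAP by 4.61 (SE 0.79). SPRR3, a cornified envelope precursor, fell by 5.55 (SE 0.77, edgeR adjusted p = 0.00348), from 367 to 7.09 CPM, and the differentiation genes KRTDAP, KRT1, SLURP1 and LY6G6C had -5.20 (SE 0.98), -4.79 (SE 0.71), -4.74 (SE 0.64) and -3.96 (SE 0.87). S100P fell by 4.35 (SE 0.51) and the defence gene LCN2 by 3.64 (SE 0.59). CDH2 rose by 3.99 (SE 0.36, edgeR adjusted p = 0.00110, higher in 5 of 6 pairs), and VIM by 1.42 (SE 0.14). The secreted and matrix genes TGFBI, COL1A1 and SPARC rose by 1.72 (SE 0.18), 1.59 (SE 0.17) and 1.94 (SE 0.35). The repressor genes SNAI2 and ZEB1 rose by 1.0 (SE 0.18) and 2.01 (SE 0.47, higher in 4 of 6 pairs), and KRT5 and KRT17 had -1.0 (SE 0.19) and -1.14 (SE 0.26).

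CDH1 had -0.35 (edgeR adjusted p = 0.339), EPCAM -0.75 (edgeR adjusted p = 0.102) and KRT14 -0.39 (edgeR adjusted p = 0.248) after TGF-B1, and EPCAM was called without the HuMEC inner pair, at -0.96. The largest rises also held SCG5 (4.90), PMEPA1 (3.93), COL4A1 (3.93) and IL32 (3.76), and the largest falls the carbonic anhydrase gene CA9 (-4.95), CDSN (-4.08), SBSN (-4.03), HOPX (-3.72) and SERPINB3 (-3.62). Of 15202 genes, 3450 were called, 1841 higher and 1609 lower with TGF-B1. Scaling by library size alone, which moved the median of all genes from 0.0115 to 0.146, called 3407, 2381 higher and 1026 lower. The count fell to 1806 without the CROP-seq inner pair, 1776 without the CROP-seq outer pair, 2074 without the MCF10A inner pair and 2153 without the MCF10A outer pair. With the inner and outer parts summed per colony, 516 genes were called over 3 pairs of colonies, 306 higher and 210 lower. FN1 (edgeR adjusted p = 0.0608), FBLN5 (0.0594), TAGLN (0.0705), KRT1 (0.0566), LY6G6C (0.0703), SNAI2 (0.0720), ZEB1 (0.145), KRT5 (0.0720) and KRT17 (0.0881) then missed the threshold with the same direction, as did FAP, SCG5, PMEPA1, COL4A1, CA9, CDSN, SBSN, HOPX and SERPINB3. TGM2, ALOX5AP, AMTN, POSTN, SPRR3, KRTDAP, SLURP1, S100P, LCN2, CDH2, VIM, TGFBI, COL1A1, SPARC and IL32 stayed called. Of the 34 called genes of the naming rule, 27 stayed called whichever pair was left out. The highest edgeR adjusted p of the other 7 were 0.0540 for CA9, 0.109 for CDSN, 0.0760 for HOPX and 0.0729 for SBSN without the CROP-seq outer pair, and 0.0559 for KRT17, 0.0764 for SERPINB3 and 0.0723 for ZEB1 without the CROP-seq inner pair.

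Matrix proteases, matrix and cytokine genes rose as groups with TGF-B1 over the 6 pairs, and keratins and differentiation genes fell. With the parts summed per colony, fry called 0 lists, with adjusted p of 0.151 or more. Matrix proteases and their inhibitors had a median of 1.42 (14 of 24 higher, 14 adjusted over the list alone, fry adjusted p = 0.00675, adjusted p = 0.201 with an estimated correlation). The sheddase gene ADAM19 had 6.00 (SE 0.41) and the stromelysin gene MMP10 5.03 (SE 0.60). Matrix genes had 1.15 (21 of 34 higher and 1 lower, 24 and 2 adjusted over the list alone). Mesenchymal markers had a median of 1.0 (13 of 23, 14 adjusted over the list alone), with the repressor gene SNAI1 at 4.36 (SE 0.46). The summed fibroblast markers were also higher with TGF-B1 in 6 of 6 pairs, from 82.3 to 264 CPM in the MCF10A inner pair and from 52.1 to 54.4 in the HuMEC outer pair, while COL3A1 stayed at 0. Actin genes had 0.86 (14 of 18, 14 adjusted over the list alone). The matrix, mesenchymal and actin lists each had fry adjusted p = 0.00799, and adjusted p = 0.201, 0.201 and 0.204 with an estimated correlation. Cytokines had 2.36 (12 of 19, 12 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.00675, adjusted p = 0.201 with an estimated correlation). Hemidesmosome genes had 0.81 (8 of 10 higher and 1 lower, 9 and 1 adjusted over the list alone, fry adjusted p = 0.0109, adjusted p = 0.249 with an estimated correlation). The laminin chain gene LAMA3 rose by 3.22 (SE 0.48). TGF-beta direct targets had 1.31 (18 of 30 higher and 3 lower, 19 and 5 adjusted over the list alone, fry adjusted p = 0.0295, adjusted p = 0.300 with an estimated correlation). YAP targets had 0.55 (8 of 18 higher and 1 lower, 10 and 1 adjusted over the list alone, fry adjusted p = 0.0360, adjusted p = 0.377 with an estimated correlation). Stratified differentiation genes had -2.37 (16 of 29, 26 adjusted over the list alone) and keratins -1.97 (7 of 11, 10 adjusted over the list alone). Both had fry adjusted p = 0.00912 and adjusted p = 0.201 with an estimated correlation, and KRT4 had -5.09 (SE 0.65). Epithelial junction genes had -0.71 (24 of 36 lower and 2 higher, 27 and 2 adjusted over the list alone, fry adjusted p = 0.00675, adjusted p = 0.201 with an estimated correlation). ELF3 had -2.20 (SE 0.39) and the adhesion gene CXADR -1.78 (SE 0.24).

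Hypoxia, immediate early, p53, ribosomal and leukocyte genes fell on balance with TGF-B1. Hypoxia genes had a median of -0.51 (12 of 21 lower, 17 adjusted over the list alone, fry adjusted p = 0.00799, adjusted p = 0.201 with an estimated correlation), with EGLN3 at -2.87 (SE 0.42). Immediate early genes had -0.39 (9 of 24 lower and 1 higher, alike adjusted over the list alone, fry adjusted p = 0.00675, adjusted p = 0.201 with an estimated correlation), with the stress factor gene ATF3 at -1.97 (SE 0.45). The p53 targets had -0.07 (7 of 20 lower and 1 higher, 8 and 3 adjusted over the list alone, fry adjusted p = 0.0360, adjusted p = 0.381 with an estimated correlation). The 1 called higher was TP53I3, at a mean of 422 CPM, with 1.08 (SE 0.13, edgeR adjusted p = 0.00179). Ribosomal proteins had -0.33 (3 of 24, 0 adjusted over the list alone, fry adjusted p = 0.0428, adjusted p = 0.527 with an estimated correlation). Leukocyte markers had -0.31 (2 of 5, fry adjusted p = 0.00675, adjusted p = 0.201 with an estimated correlation), with CD14 at -1.81 (edgeR adjusted p = 0.00249). Leaving out 1 pair raised the fry adjusted p to 0.0852 for TGF-beta targets (CROP-seq inner), 0.100 for YAP targets (CROP-seq outer), 0.131 for p53 targets (HuMEC inner) and 0.119 for ribosomal proteins (MCF10A inner). The call was lost in 5 of 6 such fits for p53 targets and for ribosomal proteins, and in 4 of 6 for TGF-beta and for YAP targets. Lists that missed the threshold were S phase (median -0.00, fry adjusted p = 0.909), G2 and M phase (0.11, 0.482), cholesterol synthesis (-0.03, 0.782), interferon-stimulated genes (0.06, 0.427), simple epithelial genes (-0.44, 0.317) and mitochondrially encoded genes (-0.09, 0.482). FBLN1 had 0.87 (edgeR adjusted p = 0.0851).

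**Figure D2:**
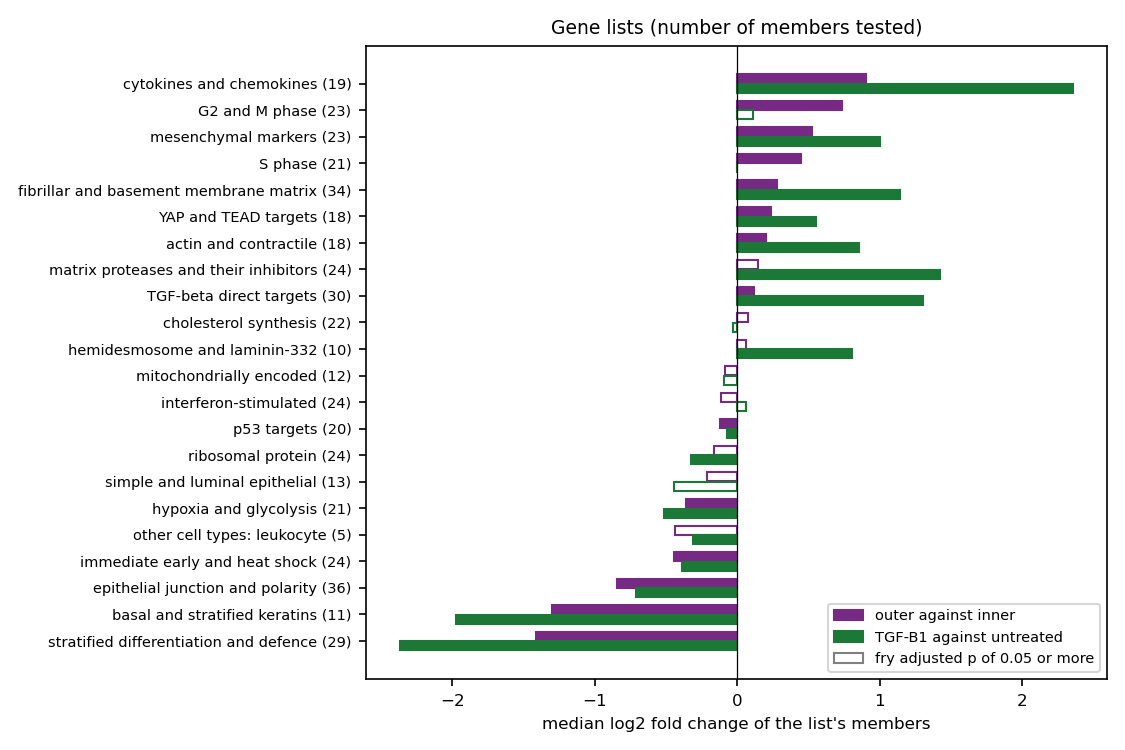
Median log2 fold change of each gene list for outer against inner (purple) and TGF-B1 against untreated (green), with open bars where the fry adjusted p is 0.05 or more and the number of genes tested in parentheses. Stratified differentiation genes lie lowest in both, at -1.41 and -2.37, and cytokines highest, at 0.90 and 2.36.

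Library medians of the per-cell score shifted toward the mesenchymal side with both position and TGF-B1, while cells of inner and outer libraries overlapped. The score is a difference, so a fall of epithelial genes alone also raises it. The mesenchymal minus epithelial score of a library's median cell was higher in the outer library in 6 of 6 pairs, by a mean of 0.0821 (SD 0.0320, range 0.0389 to 0.121). With TGF-B1 it was higher in 6 of 6 pairs, by 0.147 (SD 0.0518, range 0.0772 to 0.192). The exact two-sided sign-flip test gave p = 0.03125 for each, the smallest value that 6 pairs allow. With both positions averaged per colony, the TGF-B1 difference was positive in 3 of 3, with an exact sign-flip p = 0.25, the smallest that 3 allow. The size of the differences depends on depth, at 0.170 and 0.310 without thinning and 0.0494 and 0.0922 at a lower depth, each higher in 6 of 6 pairs. In the untreated MCF10A colony the median rose from -0.171 in the inner to -0.0811 in the outer library and with TGF-B1 from 0.00753 to 0.111, and in HuMEC from -0.203 to -0.164 and from -0.126 to -0.0776. The share of outer cells above the inner median was 78.3% and 85.9% in MCF10A without and with TGF-B1, 82.6% and 78.8% in CROP-seq and 62.7% and 67.1% in HuMEC. Thinning left out 14 to 566 cells per library that had too few UMIs.

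**Figure D3:**
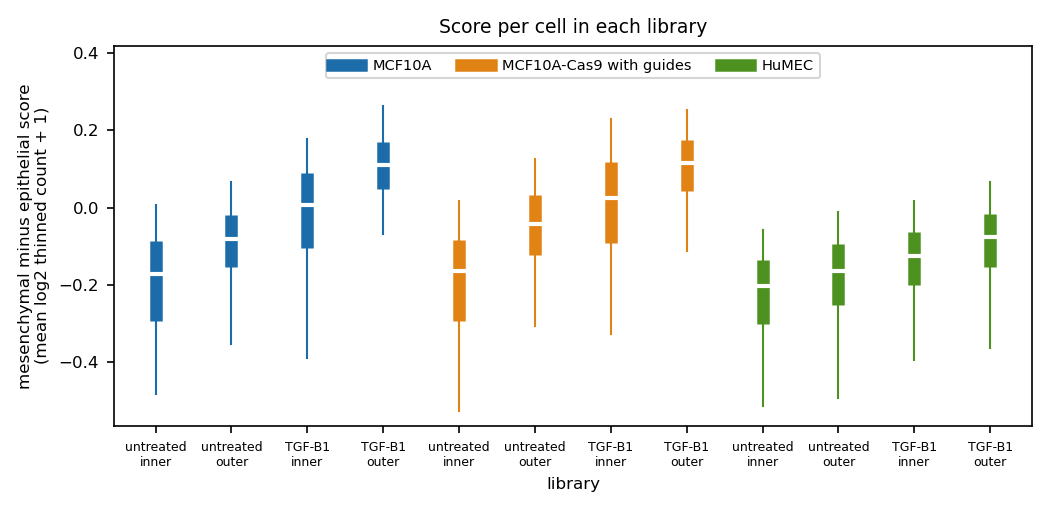
Mesenchymal minus epithelial score per cell in each of the 12 libraries, as median (white line), middle 50% of cells (thick bar) and 5th to 95th percentile (thin line), coloured by experiment. Medians run from -0.203 in the HuMEC untreated inner library to 0.115 in the CROP-seq TGF-B1 outer library.

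Whether TGF-B1 changes the position effect was tested as the difference of the effects with and without it. POSTN rose toward the edge by 4.63 (SE 0.25) in untreated colonies and by 0.47 (SE 0.17) with TGF-B1, a difference of -4.16 (SE 0.30, edgeR adjusted p = 0.00202), and was the 1 gene of 15202 called. The count depends on the libraries used, with 985 genes in the MCF10A libraries alone, 226 without a filter, and 0 to 377 with each pair left out. Its log2 ratios of outer to inner were 4.23, 4.84 and 1.87 in untreated MCF10A, CROP-seq and HuMEC, and 0.40, 0.51 and 0.62 with TGF-B1. At an unadjusted p under 0.05, 1260 genes differed. DESeq2 called 73, and without the CROP-seq untreated pair edgeR called 0 (581 at an unadjusted p under 0.05) and POSTN had -3.58 (edgeR adjusted p = 0.255). Within untreated colonies 754 genes were called for position, 396 higher and 358 lower, and within TGF-B1 colonies 260, 121 higher and 139 lower. Across 4788 genes, which are not independent replicates, the position effects without and with TGF-B1 correlated at r = 0.628 with a slope of 0.562. No list differed at a fry adjusted p under 0.05.

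Primary HuMEC and the MCF10A libraries were compared to ask whether the effects extend beyond 1 line. For position, 4 genes differed, and all 4 fell toward the edge in the MCF10A libraries. The retinoic acid-induced receptor gene GPRC5A had -1.08 in the MCF10A libraries and 0.62 in HuMEC, a difference of 1.70 (SE 0.17), and the epithelial gene C1orf116 -1.55 and 0.10, a difference of 1.65 (SE 0.15). The ectonucleotidase gene ENTPD3 and the progenitor factor gene SOX9 differed by 2.77 (SE 0.28) and 2.69 (SE 0.28), from -2.48 and -2.55 to 0.29 and 0.14, and were named after their values were seen. Each had an edgeR adjusted p = 0.0259, which became 0.497 without the HuMEC TGF-B1 pair. That fit and the one without the CROP-seq TGF-B1 pair called 0 genes, with 1041 and 2269 at an unadjusted p under 0.05, against 2253 with all pairs. Without the HuMEC untreated pair 2 were called and without the MCF10A untreated pair 7. DESeq2 called 245, and scaling by library size alone, which moved the median of all genes from 0.0482 to 0.216, called 64, 61 of them higher in HuMEC. Within the MCF10A libraries 2729 genes were called for position and within HuMEC 0 by edgeR, with 1922 at an unadjusted p under 0.05. These counts rest on 4 and 2 pairs and do not compare the size of the effects. The 2 position effects correlated at r = 0.498 across 4788 genes, with a slope of 0.347 of HuMEC on MCF10A. By fry no list was called for the difference in position effect. Median differences were 0.79 for epithelial junction genes, 1.39 for keratins and 1.33 for stratified differentiation genes (fry adjusted p = 0.156, 0.119 and 0.517). Adjusted over the list alone, 18 of 36, 6 of 11 and 8 of 29 were higher in HuMEC. A smaller fall of these lists in HuMEC is thus not excluded.

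TGF-beta direct targets rose less with TGF-B1 in HuMEC than in the MCF10A libraries. TAGLN rose by 6.56 in the MCF10A libraries and 1.85 in HuMEC, a difference of -4.71 (SE 0.55, edgeR adjusted p = 0.00541). The neuroendocrine chaperone gene SCG5 differed by -4.89 (SE 0.49, edgeR adjusted p = 0.00333), TGM2 by -5.34 (SE 0.79), FN1 by -4.80 (SE 1.04), the serine protease PRSS23 by -4.07 (SE 0.49) and the activin subunit gene INHBA by -3.96 (SE 0.79). KRT16 had -3.20 in the MCF10A libraries and -0.55 in HuMEC, a difference of 2.64 (SE 0.50, edgeR adjusted p = 0.0355), and KRT6C, CRCT1, UNC5B-AS1, RAB25 and the envelope precursor gene IVL differed by 4.64, 3.75, 3.49, 3.12 and 2.42. In HuMEC itself KRT6C, CRCT1 and IVL had 0.36, 0.52 and 0.47, and PRSS23 -0.09. Each of these 12 genes missed the threshold without 1 of the HuMEC pairs, with edgeR adjusted p from 0.0799 for SCG5 to 0.371 for FN1, both without the HuMEC inner pair. In all 410 genes differed, 125 higher and 285 lower in HuMEC, with 616 without the CROP-seq outer pair, 4 without the HuMEC inner pair, 3 without the HuMEC outer pair and 170 without the MCF10A outer pair. Scaling by library size alone moved the median of all genes by -0.168. The count was 1143 by DESeq2 and 1433 with the CROP-seq libraries reduced to non-targeting cells. Of treated CROP-seq cells with 1 guide, 27.0% in the inner and 20.5% in the outer library carried TGFBR2 guides. With the parts summed per colony 135 were called, and KRT6C, CRCT1 and RAB25 missed the threshold, at an edgeR adjusted p of 0.099, 0.0583 and 0.0901. TGF-beta direct targets differed as a group (median difference -1.44, 10 of 30 lower, 20 adjusted over the list alone, fry adjusted p = 0.00122, adjusted p = 0.00678 with an estimated correlation). Actin genes had -0.73 (2 of 18, 12 adjusted over the list alone, fry adjusted p = 0.0122, adjusted p = 0.106 with an estimated correlation). Keratins (2.49), hemidesmosome (-0.77), matrix (-0.95), YAP (-0.95) and cytokine genes (-1.76) each had fry adjusted p = 0.0363, and adjusted p = 0.159, 0.159, 0.173, 0.204 and 0.159 with an estimated correlation. Stratified differentiation genes were not called (fry adjusted p = 0.174). Within the MCF10A libraries 5649 genes were called for TGF-B1 and within HuMEC 64. The first count rests on 4 pairs and the second on 2, so the counts do not compare the size of the effects. The 2 effects correlated at r = 0.621 across 4788 genes, with a slope of 0.307 of HuMEC on MCF10A.

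The CROP-seq libraries were used to ask which genes the position and TGF-B1 responses need, starting with each targeted transcript in cells with its own guides. The TGF-beta receptor gene TGFBR2 stood at 12.3 CPM in cells with its guides against 42.0 in non-targeting cells of the TGF-B1 inner library, and at 14.1 against 41.2 in the outer library. Over both, it had a log2 fold change of -1.71 (SE 0.12, edgeR adjusted p = 4.12e-24 over targets, 504 UMIs). Without TGF-B1, TGFBR2 stood at 15.9 against 13.4 CPM in the inner and 14.1 against 14.6 in the outer library. TGFBR2 thus rose with TGF-B1 in non-targeting cells and not in cells with its guides. The difference under TGF-B1 cannot be told apart from a lost response to it. TGFBR1, the partner receptor gene, stood at 13.5 against 20.3 and 9.89 against 19.1 CPM with TGF-B1 (log2 fold change -0.80, SE 0.27, edgeR adjusted p = 0.0317, 38 UMIs), and its 8 and 2 UMIs without TGF-B1 give no usable level. Non-targeting cells held TGFBR1 at 5.35 and 3.48 CPM without TGF-B1, so it too was higher in them with TGF-B1. Of 14 targets whose own transcript could be fitted, it was lower for these 2 in the TGF-B1 arm. In the untreated arm it was lower for 0 and higher for 2, SNAI2 by 0.46 (SE 0.13, edgeR adjusted p = 0.0117) and HMGA2 by 0.56 (SE 0.20, edgeR adjusted p = 0.0365). A droplet kit reads transcripts from 1 end and counts edited ones too, so these levels check the guide labels only in part.

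Under TGF-B1, cells with guides against either TGF-beta receptor had more transcripts of cornified genes and fewer of matrix genes than non-targeting cells. The cells were summed over all guides of a target, and cells of single guides kept the TGF-B1 response to different degrees. With TGFBR2 guides FGFBP1, a growth factor carrier gene, was higher by 6.90 (SE 0.32), HOPX by 6.50 (SE 0.68) and LY6G6C by 6.48 (SE 0.82). FBLN5 had -3.64 (SE 0.14, edgeR adjusted p = 3.86e-42), ALOX5AP -3.35 (SE 0.19) and the membrane channel gene TMEM176B -3.32 (SE 0.29). With TGFBR1 guides FGFBP1 was higher by 5.41 (SE 0.42, edgeR adjusted p = 1.02e-18) and FBLN5 fell by 1.47 (SE 0.16). In all 4125 genes were called for TGFBR2, 2011 higher and 2114 lower, and 1069 for TGFBR1, 568 higher and 501 lower, a count that fell to 124 without the TGF-B1 inner library. Between the 2 targets, 1244 genes differed. In untreated cells edgeR called 0 genes for each, with 288 for TGFBR2 and 479 for TGFBR1 at an unadjusted p under 0.05, limma-voom called 0 for each, and fits with guides as units called 0 and 4. The effect with TGF-B1 differed from that without in 2706 genes for TGFBR2 and 378 for TGFBR1. The arms held different mixes of TGFBR2 guides, with 51 untreated and 1099 treated cells for 1 guide and 125 and 78 for another. The untreated counts and the difference between arms thus do not compare the same mix. Stratified differentiation genes were higher with TGFBR2 guides (median 4.12, 14 of 18 higher and 1 lower, 16 adjusted over the list alone) and with TGFBR1 guides (median 2.26, 9 of 18, 10 adjusted over the list alone), each with adjusted p = 0.00417 with an estimated correlation. Matrix genes were lower with TGFBR2 guides (median -1.51, 20 of 23 lower and 2 higher, 22 adjusted over the list alone, adjusted p = 0.00219 with an estimated correlation). With TGFBR1 guides they were lower as well (median -0.63, 15 of 23 lower and 1 higher, 16 adjusted over the list alone, adjusted p = 0.0104 with an estimated correlation).

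Among the other targets, epithelial genes were higher in cells with ZEB1 guides under TGF-B1 and lower in cells with FOXA1 guides without it. With ZEB1 guides 19 genes were called in the TGF-B1 arm, 15 higher and 4 lower, among them S100A14 (1.36, SE 0.18, edgeR adjusted p = 4.22e-07), the polarity gene CRB3 (1.37, SE 0.32, edgeR adjusted p = 0.0242) and TMEM40 (1.46, SE 0.27, edgeR adjusted p = 0.00120). Epithelial junction genes rose by a median of 0.52 with them (3 of 28, 9 adjusted over the list alone, fry adjusted p = 0.00264, adjusted p = 0.00662 with an estimated correlation). Without the TGF-B1 outer library CRB3 and TMEM40 had edgeR adjusted p = 0.898 and 0.257, and S100A14 stayed called at 0.671, since its log2 ratio was 0.684 in the inner and 1.94 in the outer library. The ZEB1 count was 2 without that library and 0 with guides as units (615 at an unadjusted p under 0.05, 34 by limma-voom). With FOXA1 guides 40 genes were called in the untreated arm, 2 higher and 38 lower, with HOPX at -2.40 (SE 0.40, edgeR adjusted p = 0.000281) and the envelope gene CNFN at -3.13 (SE 0.69, edgeR adjusted p = 0.00896). Stratified differentiation genes had -0.90 there (6 of 18, 15 adjusted over the list alone, fry adjusted p = 0.00987, adjusted p = 0.0236 with an estimated correlation). Epithelial junction genes had -0.31 (4 of 28, 11 adjusted over the list alone, fry adjusted p = 0.0031, adjusted p = 0.0379 with an estimated correlation). FOXA1 itself had 4 UMIs in cells with its guides and 29 in non-targeting cells of that arm, too few to check the guides by its level. Without the TGF-B1 outer library CNFN had edgeR adjusted p = 0.0733. The FOXA1 count was 25 without the untreated inner library and 1 with guides as units. ZEB2 guides gave 22 calls in the untreated arm, 21 of them lower, with FN1 at -1.32 (SE 0.28, edgeR adjusted p = 0.00650), and 5 without the untreated outer library. They gave 8 in the TGF-B1 arm, 6 of them lower, which became 0 without the TGF-B1 outer library (441 at an unadjusted p under 0.05). SNAI1 guides gave 16 in the untreated arm, 11 higher and 5 lower (9 and 7 by library size alone, 6 calls without the untreated inner library), with FN1 at 1.44 (SE 0.32, edgeR adjusted p = 0.0195). SNAI1 itself had 0 UMIs in these cells and 3 in non-targeting cells of that arm, too few to check the guides by its level. Without the untreated outer library FN1 had edgeR adjusted p = 1.0 with ZEB2 and 0.695 with SNAI1 guides. The difference between arms was tested for ZEB1 and ZEB2, and edgeR called 0 genes for each, with 298 and 182 at an unadjusted p under 0.05. For EGFR guides in the TGF-B1 arm the interferon list rose by a median of 0.43 (0 of 13, 7 adjusted over the list alone, fry adjusted p = 0.00265, adjusted p = 0.0104 with an estimated correlation).

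The response indices measure each target against non-targeting cells at 0, in units of the response of MCF10A cells without guides. The TGF-B1 index was -0.588 in the inner and -0.536 in the outer library for TGFBR2 guides, and -0.330 and -0.159 for TGFBR1 guides. Single non-targeting guides ran from -0.0518 to 0.113 in the inner and from -0.0130 to 0.0325 in the outer library. The position index of the TGF-B1 arm was -0.875 and -0.743 for TGFBR2 and -0.505 and -0.200 for TGFBR1, against -0.174 to 0.353 and -0.0570 to 0.122 for single non-targeting guides. The other 37 targets did not fall below the range in both libraries for either index, and in the untreated arm 0 of 39 targets did for the position index. The position and TGF-B1 effects correlated at r = 0.62 across 4788 genes, with a slope of 1.15 of TGF-B1 on position. Loss of the TGF-B1 response alone can thus lower the position index. On the position scale TGF-B1 moved non-targeting cells by 1.43 in the inner and 1.16 in the outer library. It moved cells with TGFBR2 guides by 0.521 and 0.397, so a smaller shift with TGF-B1 goes with their lower index. The index compares cells within 1 library, so it does not show what the difference between outer and inner cells needs. No p-value was computed for the indices.

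**Figure D4:**
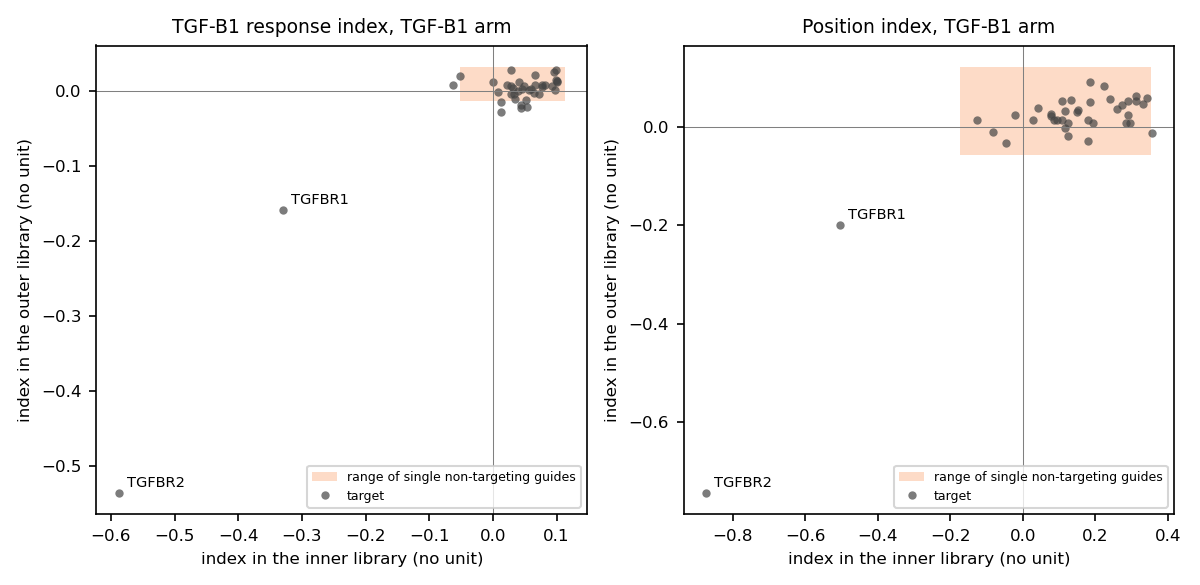
TGF-B1 response index (left) and position index (right) of each target in the inner (x axis) and outer (y axis) library of the TGF-B1 arm, without units, with the range of single non-targeting guides shaded. TGFBR2 lies lowest at -0.588 and -0.536 (left), and TGFBR1 follows at -0.330 and -0.159.

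Whether a target changes how many cells reach the edge was read from the odds ratio of outer to inner cells relative to non-targeting guides. Without TGF-B1, cells with ZEB2 guides were more common in the outer library (odds ratio 1.55, 95% interval 1.33 to 1.82, 411 inner and 596 outer cells), as were those with SNAI2 (1.42, 1.18 to 1.73) and FOXO3 guides (1.34, 1.02 to 1.76). IL6R (0.652, 0.454 to 0.931), TRIM28 (0.678, 0.479 to 0.954) and FZD7 guides (0.699, 0.506 to 0.960) were less common there. With TGF-B1, FGFR1 (0.18, 0.0995 to 0.309), HMGA2 (0.518, 0.306 to 0.865), TGFBR2 (0.680, 0.582 to 0.793, 1239 inner and 1098 outer cells) and TGFBR1 guides (0.720, 0.530 to 0.976) were less common in the outer library. Without the largest guide of the target, the interval came to include 1 for FGFR1, with 77 inner and 18 outer cells (0.671, 0.205 to 2.14), for SNAI2 (1.16, 0.902 to 1.5), FOXO3 (1.28, 0.889 to 1.84), IL6R (0.627, 0.360 to 1.07) and TGFBR1 (0.83, 0.564 to 1.22). The other 34 targets of the untreated arm and 36 of the TGF-B1 arm had intervals that include 1. With the largest guide of each target left out, 3 lay above 1 and 7 below in the untreated arm and 3 above and 6 below with TGF-B1. With all other targets as reference, 4 lay above and 8 below untreated, and 7 above and 3 below with TGF-B1. The intervals hold counting error only, and single non-targeting guides ran from 0.488 to 1.31 without and from 0.434 to 2.47 with TGF-B1. Across 40 targets the log odds ratios of the arms had r = 0.214 (permutation p = 0.189) and rho = 0.197 (permutation p = 0.221), and r = 0.262 (permutation p = 0.113) without ZEB2 and IL6R.

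**Figure D5:**
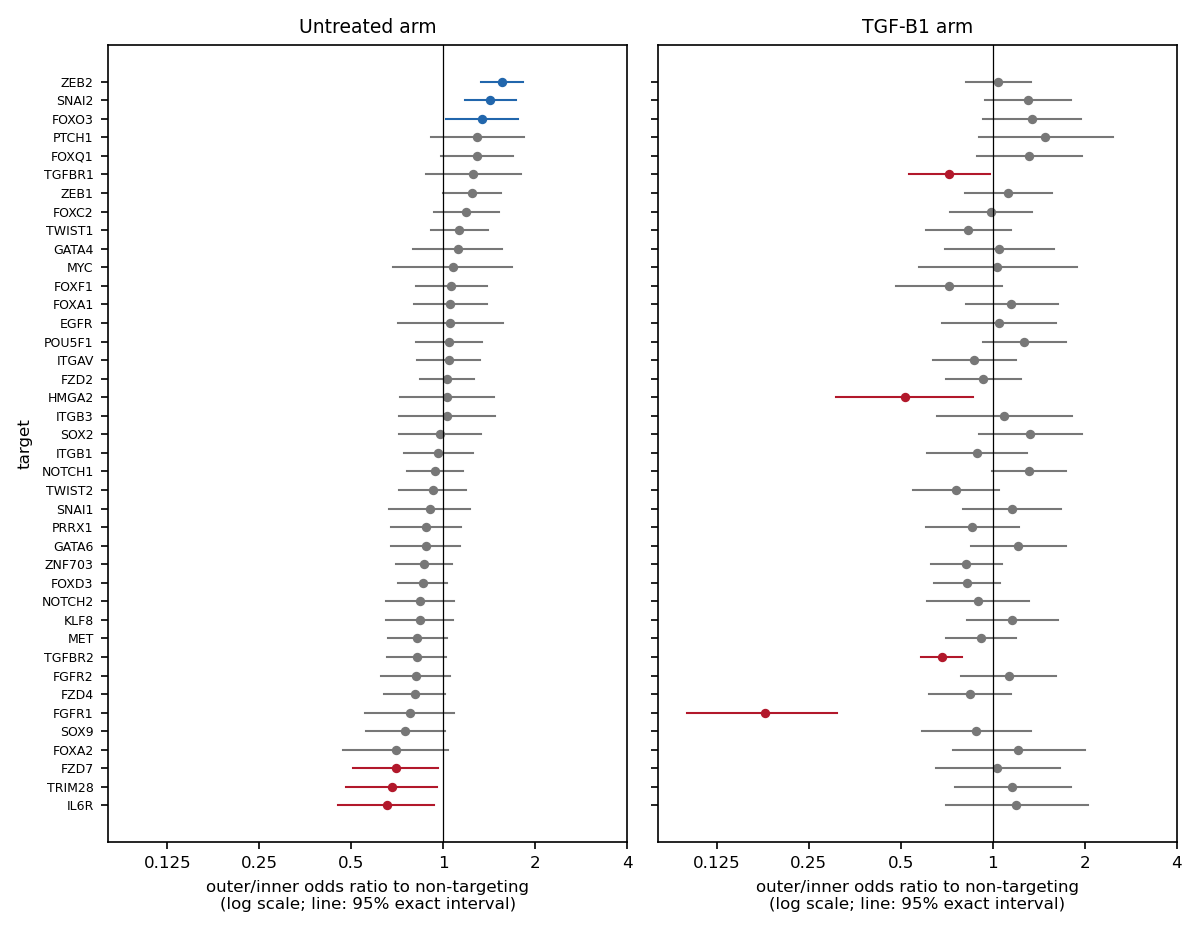
Odds ratio of outer to inner cells of each target relative to non-targeting guides (points, log axis) with exact 95% intervals (lines), without (left) and with TGF-B1 (right), blue where the interval lies above 1 and red where it lies below. ZEB2 has 1.55 on the left and FGFR1 0.18 on the right.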

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

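Results are given here where the effects of 2 groups differed by a test of the difference itself, or where cells lay outside every comparison. The tests of differences between treatments and between cell sources were fixed beforehand. Those of receptor guides with against without TGF-B1 were not among them, nor were the fits with the parts summed per colony. The naming of ENTPD3 and SOX9 followed from their values. POSTN, a matricellular gene raised by TGF-B1, was the 1 gene whose position effect differed with and without it over all 6 pairs, by -4.16 on the log2 scale, and without the CROP-seq untreated pair it missed the threshold at -3.58. The MCF10A libraries alone called 985 genes, and leaving out each pair 0 to 377. The 10 ways of splitting the 6 pairs are too few for a share under 0.05, and the highest count among the others was 0. TGF-B1 raised POSTN by 9.48, 6.70 and 4.73 in the inner pairs of MCF10A, CROP-seq and HuMEC and by 5.65, 2.37 and 3.48 in the outer pairs, and no explanation was tested.

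The position effect of 4 genes differed between HuMEC and the MCF10A libraries, by 1.70 for GPRC5A, 1.65 for C1orf116, 2.77 for ENTPD3 and 2.69 for SOX9. Each had a negative position effect in the MCF10A libraries. In HuMEC the effect was 0.62 (SE 0.14) for GPRC5A. For C1orf116, ENTPD3 and SOX9 it was 0.10 (SE 0.12), 0.29 (SE 0.22) and 0.14 (SE 0.22), too close to 0 to show a rise. Each gene missed the threshold without the HuMEC TGF-B1 pair, which leaves 1 HuMEC pair. The 15 splits of the pairs are too few for a share under 0.05, and 3 of them, the real one included, called at least 4 genes. The highest count, 726, came from setting the untreated pairs of the MCF10A and CROP-seq experiments against the other 4 pairs. What that split reflects was not tested.

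The TGF-B1 effect of 410 genes differed between HuMEC and the MCF10A libraries. The largest negative differences of HuMEC from the MCF10A libraries were -5.34 for TGM2, -4.89 for SCG5, -4.80 for FN1, -4.71 for TAGLN, -4.07 for PRSS23 and -3.96 for INHBA. The largest positive ones were 4.64 for KRT6C, 3.75 for CRCT1, 3.49 for UNC5B-AS1, 3.12 for RAB25, 2.64 for KRT16 and 2.42 for IVL. In HuMEC itself KRT6C, CRCT1 and IVL had 0.36, 0.52 and 0.47, and PRSS23 -0.09. Matrix and actin genes as lists had adjusted p = 0.173 and 0.106 with an estimated correlation. Without the HuMEC inner pair 4 genes were called, without the HuMEC outer pair 3, and with the inner and outer parts summed per colony 135. Each of these 3 fits leaves only 1 HuMEC pair, whose spread is assumed to be that of the MCF10A pairs. The other 14 of the 15 splits called at most 7 genes, and 15 are too few for a share under 0.05. Primary cells and an immortalised line differ in many ways, so the cell type, the experiment and the culture cannot be separated by this design.

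The effect of receptor guides on other genes differed with and without TGF-B1 in 2706 genes for TGFBR2 and 378 for TGFBR1. The untreated cells had few TGFBR1 transcripts, at 8 and 2 UMIs in cells with its guides, and fewer cells carried receptor guides there. Guides 3 and 4 against TGFBR2, whose cells kept all or part of the response, had 125 and 110 untreated and 78 and 129 treated cells. Guide 6 had 51 and 1099, so the arms compare different mixes of guides. Outside the comparisons lay 14713 cells of the MCF10A matrix that no cell table assigns to a library, 2379 CROP-seq cells with more than 1 guide and 3248 with none. In 30 sets of 6 pairs, for the score and the 14 always named genes, a search for an outlying pair found 0. It cannot show that the pairs are alike, since the 2 HuMEC pairs can differ together and escape it. FN1 rose with TGF-B1 by 7.29 in the MCF10A libraries and by 2.49 in HuMEC.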

How the results depend on the processing

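The non-targeting, newer-fit and per-colony alternatives were chosen after the data had been seen, and all others before. Over the alternatives, including each pair or library left out, named genes and list members kept their direction and call in 3156 results, kept the direction but lost the call in 448, gained a call in 23 and reversed in 5. Gene lists did so in 279, 85, 2 and 8. Unless a clause says so, the cause was not tested.

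Counts of called genes moved most. For position, 718 genes were called of those with a mean of at least 20 CPM, where fewer genes were tested, 574 with experiment and treatment as additive terms, and 680 to 1744 with each pair left out. For TGF-B1 these were 1333 at 20 CPM, 516 with the parts summed per colony and 1776 to 3912. The interaction had 73 by DESeq2, 226 without a filter, 6 after thinning, 985 in the MCF10A libraries alone, 3 with non-targeting cells only, and 0 to 377 with each pair left out. The position difference of HuMEC had 64 by library size alone, 245 by DESeq2, 148 without a filter, 10 at 20 CPM, 12 after thinning, 21 with non-targeting cells only, and 0 to 7 with each pair left out. The TGF-B1 difference of HuMEC had 1143 by DESeq2, 903 without a filter, 155 at 20 CPM, 1433 with non-targeting cells only, 135 with the parts summed per colony, and 3 to 616. Camera with an estimated correlation called 0 of the 14 position lists and 0 of the 16 TGF-B1 lists, fry with the parts summed per colony 0 of these 16, and the MCF10A libraries alone gave 7 position lists.

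For guide targets, the 133 calls of the untreated arm became 311 with the newer fit, 630 by limma-voom, 41 with guides as units and 196 to 423 with each library left out. The 1069 of TGFBR1 became 537 with guides as units and 124 to 986. Leaving out a library leaves its arm with 1, which is then assumed to vary like the others. The TGF-B1 index of TGFBR2, -0.562 on average, became -0.477 with a larger prior count and -0.767 with the HuMEC signature, and its position index, -0.809, became -0.595 and -0.508. The HuMEC signature put 3 targets below the non-targeting range for position in the untreated arm, against 0. Intervals below 1 in the untreated arm numbered 8 with all other targets as reference and 7 without the largest guides, against 3, and above 1 with TGF-B1 7 and 3, against 0.

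KRT14, not called for position, ran from -0.277 without the MCF10A untreated pair to 0.0808 without the CROP-seq TGF-B1 pair, with 0.0116 in the MCF10A libraries alone, and TGFBI from -0.0591 without the CROP-seq untreated pair to 0.175. Among lists not called, cholesterol synthesis reversed to -0.0467 for position in the MCF10A libraries alone, and with each pair left out ran from -0.0628 to 0.0859 for TGF-B1. Mitochondrial genes ran from -0.122 to -0.018 for position, where the direction of fry reversed in the last. For TGF-B1, S phase genes ran from -0.109 to 0.106, with 0.0558 summed per colony, and G2 and M phase genes from 0.0319 to 0.190, with -0.0393 in the MCF10A libraries alone. With TGFBR1 guides LY6G6C ran from -1.64 without the TGF-B1 inner library to 5.81 without the outer, each then resting on 1 library. Depth limits genes with few UMIs, such as TGFBR1 in untreated cells.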

Other observations

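The test of TGF-B1 against untreated shares of guides, the fibroblast, depth and low-quality tests, the outgrowth test and the comparison of treated with untreated cells on the index scale were chosen after the results had been seen, and the others before. Cells with TGFBR2 guides were far more common after TGF-B1, and those with TGFBR1 guides were so to a smaller degree. Those with TGFBR2 guides made up 3.19% of untreated and 27.0% of treated cells in the inner libraries (odds ratio to non-targeting guides 13.1, exact 95% interval 10.8 to 15.7) and 2.59% and 20.5% in the outer libraries (10.8, 8.92 to 13.2). Cells with TGFBR1 guides had odds ratios of 4.18 (2.98 to 5.88) and 2.40 (1.73 to 3.33). Cells with guides against SNAI2, the repressor gene whose product is also called Slug, were less common after TGF-B1, at 0.725 (0.540 to 0.966) in the inner and 0.663 (0.522 to 0.837) in the outer libraries. Those with ZEB2 guides were less common in the outer libraries, at 0.658 (0.544 to 0.796), but not in the inner, at 0.983 (0.789 to 1.22). Beside the receptors, intervals lay above 1 in both positions for EGFR (1.82 and 1.81, 5 of 5 guides above 1), MET (1.49 and 1.66, 3 of 6) and ZNF703 guides (1.45 and 1.37, 5 of 6). The single guides against SNAI2 did not agree, with 3 of 6 above 1 and ratios from 0.406 to 2.56, and 2 of the 6 against ZEB2 lay above 1. Single guides against TGFBR2 differed widely, with treated to untreated ratios of 12.9, 28.7, 1.26, 2.37, 29.3 and 43.5 for guides 1 to 6, relative to non-targeting guides, and TGFBR2 stood at 9.39, 14.7, 39.5, 25.2, 6.52 and 13.3 CPM in their treated cells.

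Genes of stratified differentiation summed to 18370 CPM in the centre and 9712 at the edge of the untreated MCF10A colony, and to 3556 and 1631 with TGF-B1. In HuMEC they summed to 18360 and 12860 without, and 12400 and 12440 with TGF-B1, so that the treated colony had no lower sum at its edge. Epithelial junction genes summed to 4834 and 3267 CPM in MCF10A and 3569 and 1803 with TGF-B1, and in HuMEC to 6976 and 5869, and 5281 and 4378. IL6, a cytokine gene at a mean of 0.72 CPM, rose by 7.21 with TGF-B1 and was higher in 5 of 6 pairs. Position raised IL6 by 2.06 (edgeR adjusted p = 0.0356, but 0.201 without the CROP-seq TGF-B1 pair).

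In the outer colony stratified differentiation genes were lower (fry adjusted p = 0.0146, adjusted p = 0.127 with an estimated correlation) and matrix genes higher (fry adjusted p = 0.0267, 0.0955 without the HuMEC untreated pair, adjusted p = 0.205 with an estimated correlation). Of the 32 splits that swap inner and outer within pairs, only the real one called as many as 1707 genes. The highest other count was 5. This argues against a grouping by chance but cannot exclude it, since 1 of 32 is the smallest share these splits allow. For fibroblasts in the outer libraries, 0 of 6 outer libraries had a summed CPM of at least 1 for COL3A1 and LUM, abundant fibroblast transcripts, and the highest sum in any library was 0.0089, which argues against them. All 10 fibroblast markers together were higher in the outer library in 3 of 6 pairs, the untreated ones. For depth, 1409 of the 1707 genes were still called with all libraries thinned to 1 total, and without cells of few UMIs 1668 were, which argues against either as the whole cause. A response of the cells to the free edge stays untested, cell density was not measured, and the cell cycle was not separated from position.

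For TGF-B1 against untreated, 3450 genes were called over the 6 pairs and 516 with the inner and outer parts summed per colony. With both parts of a colony kept together there are 4 splits, too few for a share under 0.05, and the highest count among the others was 4. Cells with TGFBR2 guides had a TGF-B1 index of -0.588 and -0.536. Summed over cells, their treated against untreated value on that scale was 0.304 in the inner and 0.205 in the outer library, against 0.891 and 0.752 in non-targeting cells. The median treated cell with TGFBR2 guides scored -0.163 and -0.0450, near the -0.188 and -0.0632 of untreated and far from the 0.251 and 0.306 of treated non-targeting cells. Guides that do not cut may explain part of the remaining response, since guide 3, or 1 of 6, had cells with median scores inside the non-targeting range in both libraries and 0% below the midpoint of untreated and treated non-targeting medians, against 94.0% and 89.2% for guide 1 and 50% and 57.9% for guide 4. Across guides, the pooled TGFBR2 cells thus mixed low scores with scores like those of treated non-targeting cells. Whether cells of 1 guide mix a working and a lost receptor stays open, since receptor protein was not measured. The pooled cells had an SD at least 2.61 times that of treated non-targeting cells. Of them 88.9% and 87.6% lay below the midpoint, outside the 20% to 80% set for a mixture, so this test cannot tell. Guide 4 and cells with TGFBR1 guides (53.2% and 27.4%) lay inside it. Untreated non-targeting cells of the inner library had an SD of 0.373, so a spread of this size also goes with a low score. TGFBR1 guides differed too, with 76% and 43.6% below the midpoint for guide 5 and 15.4% and 5% for guide 2. Guide 3 against TGFBR1 had 0% in the outer library.

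The larger share of cells with TGFBR2 guides after TGF-B1 was weighed against chance. Random drift is argued against by 0 of 151 single guides reaching the median TGFBR2 ratio, 20.4 with 0.5 cells added to each count, or 7.62 for the 4 TGFBR2 guides with at least 20 untreated cells. These guides were non-targeting or against targets other than the 2 receptors, had at least 20 untreated cells, and ran from 0.346 to 3.01. Such guides against TGFBR1 reached 4.32. Among guides of the same targets with 1 to 19 untreated cells, the highest ratio was 10.1 for a KLF8 guide with 2 untreated and 10 treated cells. One non-targeting guide, with 13 untreated and 30 treated cells, had 4.65, above the highest TGFBR1 value of 4.32. A GATA4 and an HMGA2 guide had 0 untreated and 4 and 3 treated cells, which give no usable ratio. Outgrowth of 1 guide or clone is argued against by 2 of the 4 TGFBR2 guides with at least 20 untreated cells, at 12.9 and 43.5, which lay above all 151, while the other 2, at 1.26 and 2.37, lay inside their range. No biological explanation of the share was tested, and cell numbers were not measured.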
